A study of Homo sapiens with 6 samples.

How the data were processed

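The data came from a pooled CRISPR knockout screen in CHP212, an established human neuroblastoma cell line. Per the labels' protocols, cells were transduced with the GeCKOv2 libraries A and B, in which each lentivirus carries a guide RNA that directs Cas9 to a chosen gene. They then went through puromycin selection and 10 days of recovery. The 3 DMSO samples were exposed to 0.2% DMSO, the solvent, for 48 h and collected without further culture. The 3 Nutlin samples were exposed to 10 µM Nutlin-3a, a small molecule that keeps MDM2 from binding p53, for 48 h, in 2 rounds with a recovery after each, and then collected. The guide cassette was amplified from genomic DNA and sequenced, so the reads of a guide track how many cells carried it.

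The deposited values are raw counts of reads per guide, whole numbers without normalization, for 6 libraries. The submitters' processing notes name bcl2fastq 1.8.4, FastQC 0.11.2 and Bowtie2 2.2.3. How reads were matched to guides is not given in the sources used here, nor are guide sequences or a genome build. No molecular identifiers are described, and PCR reads are not independent molecules, so count floors cover counting error only. The table held 119460 guides under 21696 labels. These were 1000 non-targeting control guides, 6835 guides to 1795 microRNA genes, and guides to 18901 other genes, 6 guides per gene in most cases. Of the 18901 gene names, 17372 were current symbols in the RefSeq annotation of the human assembly GRCh38.p14, 1349 were older names with 1 current match and 180 had no match. Names are given as in the table, with the current symbol where it differs.

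Guide counts were compared with edgeR 4.0.16 in R 4.3.3, Nutlin over DMSO, with no covariate. Library sizes were scaled with TMM factors. Guides were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which kept 86484 guides and left out 32976, of which 6739 had no read in any library. The robust quasi-likelihood test was two-sided, with Benjamini-Hochberg adjustment over guides and a threshold of 0.05. A guide with no read in any Nutlin library has a fitted fold change that depends on the prior count, so its reads are given in place of a fold.

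Genes with at least 3 tested guides were scored by robust rank aggregation, separately in each direction and one-sided. Guides were ranked by their one-sided p, and only ranks in the top 25% entered the score. P-values came from 100000 random guide sets of the same size, adjusted over 18121 genes. The smallest p this gives is 1e-05, and the smallest adjusted p that 1 gene alone can reach is 0.181, so that 4 genes at the smallest p would be needed for any call. The exact null distribution of the same score was therefore added after the data were seen. Lists of genes were compared with all other tested guides by camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 between guides, adjusted over 27 lists. Beside it stand camera with an estimated correlation, fry, and the gene test adjusted over the list alone. The evenness of guide reads was compared between groups by exact two-sided permutation tests, which with 3 libraries against 3 cannot go below p = 0.1. Non-targeting and targeting guides were compared with Fisher's exact test over guides, which are not independent replicates. Whether guides of the same gene concurred beyond chance was checked with 1000 shuffles of gene names over guides, a check added after the data were seen.

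The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 15 genes with the smallest p in the higher direction and the 10 in the lower direction, whether or not they passed. It added 13 genes of the p53 pathway in every case, among them MDM2, MDM4, CDKN1A, BAX, BBC3, PMAIP1, USP28, ATM, CHEK2, PPM1D and USP7. It further took list members that passed and the 2 most extreme members of each list, genes with 3 or more called guides, and the 10 single guides with the largest fold change that were higher in every Nutlin than in every DMSO library. The value of a gene is the median log2 fold change of its tested guides. Reads of a gene are summed over its tested guides and given as CPM, scaled to the library total.

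Alternatives were edgeR's RLE factors, library totals without composition factors, TMM factors from non-targeting guides, no filter, a DMSO mean of at least 50 counts, the replicate number as a block, each library left out, and DESeq2 1.42.0. For genes, they were summed counts, fry per gene, the top 10% of guides, omission of the best guide of each gene, and each of the libraries A and B alone. Camera on ranks and an odds ratio of non-targeting guides within 20 strata of DMSO count were added after the data were seen. The procedure was tested on simulated data. With independent noise, 98% of genes with a 4-fold change were called by the exact null. In a further setting every guide, changed or not, was also given a fold change drawn from the non-targeting guides. Then 2.04% of genes with a 4-fold change and 16.3% with a 16-fold change were called. With a 64-fold change 84% were called and with a 256-fold change 100%, and 1 of 17834 unchanged genes was called. The log2 fold changes of non-targeting guides had an SD of 3.02, against 3.54 for targeting guides, so the fold changes drawn were narrower than those of targeting guides. The SD after simulation was not computed. Unchanged guides in this setting were called higher in 14.3% and lower in 35.7% of cases, against 12.4% and 35.2% of all tested guides. Where a gene changed 256-fold alone, 39 of 50 such genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.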

Results

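Guide reads were counted in 3 libraries of CHP212 neuroblastoma cells exposed to DMSO and 3 libraries of cells that had been through 2 rounds of Nutlin-3a. The series states that its purpose was to find positive modulators of p53 function. Guides whose cells survive or grow through Nutlin-3a take a larger share of the reads. Library totals were 34286541, 23995151 and 21447960 reads for DMSO replicates 1, 2 and 3, and 23575683, 18547689 and 13664994 reads for Nutlin replicates 1, 2 and 3. Levels are given as CPM, the reads of a guide scaled to the library total. A count of 0 in a library allows a level of up to 0.0875 to 0.220 CPM, depending on its depth. Nutlin samples were also cultured for longer than DMSO samples, so that time in culture and treatment cannot be told apart. The labels do not say whether the replicates were transduced separately. The p-values of the guide test measure only the spread between these libraries, and those of rank aggregation and camera compare guides with other guides.

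Guides to several genes that carry out p53-driven cell death were called higher. The list of pro-apoptotic genes shifted upward relative to other guides (camera adjusted p = 0.00842), with 35 of its 124 tested guides called higher (28.2%, against 12.4% of all tested guides) and 36 called lower. With an estimated correlation the list had an adjusted p = 0.0938, and it also missed the threshold with library totals (adjusted p = 0.0971), with the replicate number as a block (adjusted p = 0.0827) and on ranks, an alternative added after the data were seen (adjusted p = 0.765). The camera shift was relative to other guides, since the median log2 fold change of the list was −0.79 and its mean −1.01. Fry, which tests a list against 0, nevertheless called it higher (fry adjusted p = 0.000377). No member passed over all genes tested, and 4 of 26 passed adjusted over the list alone: APAF1, BBC3, BAX and PMAIP1. BBC3 and PMAIP1 encode the BH3-only proteins PUMA and NOXA, and BAX forms pores in mitochondria. BBC3 had 139 ± 5.50 CPM with DMSO and 861 ± 94.7 with Nutlin, with 2 of 4 guides called higher and 1 called lower. BAX had 4 of 6 guides called higher but 94.6 ± 3.80 and 80.7 ± 6.42 CPM. PMAIP1 had 3 guides called higher and 2 lower of 6, and 136 and 166 CPM. Median log2 fold changes were 2.06 for BBC3, 1.804 for BAX and 1.51 for PMAIP1, but turned negative when scaled to library totals, at −0.72, −0.98 and −1.27, where the median guide was at −4.07. APAF1, the core of the apoptosome, rested on 1 guide, HGLibA_02366, which went from 159 to 9209 CPM, and 1 of its 5 guides was called lower. Single guides to SNAP47 and ARHGAP40, which are not on this list, had like levels, from 158 to 9609 and from 162 to 9522 CPM.

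The list of genes that restrain RAS and MAPK signalling also shifted upward (camera adjusted p = 0.00305, 23 of 78 guides higher, 29.5%, and 27 lower). Its median was −0.50 and its mean −1.54, so the camera shift was again relative to other guides. Fry also called this list higher (fry adjusted p = 0.000247). With an estimated correlation this list had an adjusted p = 0.0938, with the replicate number as a block adjusted p = 0.120, and on ranks adjusted p = 0.765. Of its 16 members, DUSP4, KCTD20 and CIC passed adjusted over the list alone and none over all genes. KCTD20 had 3 of 4 guides called higher on the TMM scale but lower CPM with Nutlin, 297 with DMSO and 87.7 with Nutlin. CIC, a transcriptional repressor downstream of ERK, had 3 of 6 guides called higher and 162 and 294 CPM. SPRY1, an inhibitor of receptor tyrosine kinase signalling, chosen here after its values were seen, had 3 of 5 guides called higher and 1 called lower, with 72.2 and 298 CPM. RASA1, a RAS GTPase activator, and LZTR1, an adaptor for RAS degradation, were the most extreme members, with 32.1 and 0.385 CPM for RASA1 and 16.3 and 1.47 CPM for LZTR1, and neither passed.

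Guides to other regulators of p53 were called in both directions. None of the other 25 lists passed with camera, and their smallest adjusted p was 0.711. Among p53 activators and cofactors 17 of 111 guides were called higher (15.3%) and 36 lower (32.4%), near the 12.4% and 35.2% of all tested guides. Adjusted over their lists alone, USP22 passed as higher, and HDAC1, a histone deacetylase, and COPS4 passed as lower. CDKN1A, the p21 cell cycle inhibitor induced by p53, had 1 of 3 guides called higher and a median of −1.07. USP28, a deubiquitinase of the mitotic stress response, had a median of −0.09, with 2 of 5 guides called higher and 1 called lower. The kinase genes ATM and CHEK2, which act on p53 after DNA damage, had medians of −1.26 and −2.04, and CHEK2 had 3 of 6 guides called lower. Of the genes that hold p53 back, MDM4 and USP7 had medians of −0.63 and −0.66 with 1 guide called in each direction. MDM2 and PPM1D had too few tested guides for the gene test, with 1 and 2 tested. Fry, which tests a list against 0 rather than against other guides, called the 2 lists above higher and 23 lower.

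**Figure D1:**
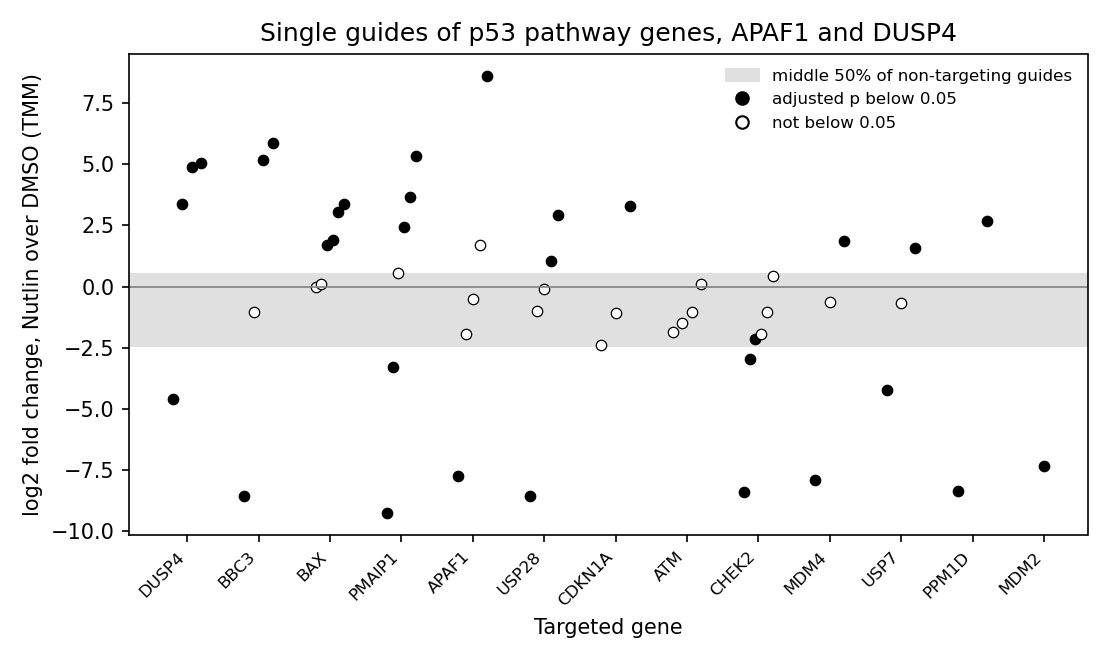
Log2 fold change, Nutlin over DMSO, of each tested guide of named p53 pathway genes, APAF1 and DUSP4, one point per guide, filled where called, with the middle 50% of non-targeting guides shaded. The 8 lowest points belong to guides with no read in any Nutlin library, whose fitted value depends on the prior count, and on library totals the medians of BAX (1.804), BBC3 (2.06) and PMAIP1 (1.51) turn negative.

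Few genes were called when the concordance of a gene's guides was tested. By rank aggregation with random guide sets 0 of 18121 genes passed as higher and 0 as lower. At an unadjusted p below 0.05 there were 882 genes in the higher and 871 in the lower direction, where chance gives 5% of genes. With the exact null of the same score, added after the data were seen, 1 gene passed as higher and 0 as lower. With library B guides alone 1 gene passed as higher, and 0 did with library A guides alone. When every gene lost its best guide 0 passed, but the null took no account of that loss, so this count cannot show whether guides concur. Tests that do not ask whether guides concur gave far larger counts. EdgeR on summed gene counts called 5730 genes higher and 5735 lower, and fry per gene called 2005 higher and 9550 lower.

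Other genes near the top of the ranking did not pass, with exact adjusted p from 0.462 to 0.804. Of these, IFRD1, a transcriptional coregulator, had 121 ± 6.81 CPM with DMSO and 817 ± 48.2 with Nutlin (SD, n = 3). HSF2BP, a meiotic recombination factor, had 118 and 1433, and GPATCH8 had 78.9 and 913. USP22, the deubiquitinase of the SAGA complex, had 4 of 6 guides called higher and 117 and 159 CPM. DUSP4, a phosphatase that inactivates ERK, had 3 of 4 guides called higher and 1 called lower, with 137 and 614 CPM. The same range of p held C10orf90, PRKCB, HIP1, PTAR1, GLTPD2, hsa-mir-422a, GPR133 (now ADGRD1), OR10A5 and HSBP1L1. PRKCB, a protein kinase C, and GPR133, an adhesion receptor, each had 5 of 6 guides called higher on the TMM scale but lower CPM with Nutlin, 67.2 and 30.3 for PRKCB and 238 and 162 for GPR133. There were 261 genes with 3 or more guides called higher, against 228 on average when gene names were shuffled (permutation p = 0.00699, adjusted over 8 such counts p = 0.052). In the lower direction 3368 genes had 3 or more guides called, against 3435 on average when shuffled (permutation p = 0.975).

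In the lower direction MBTPS2, the site-2 protease of sterol signalling, had 28.0 ± 2.94 CPM with DMSO and no read with Nutlin in its 3 tested guides. COPS4, a subunit of the COP9 signalosome, had 60.4 ± 3.61 and 1.66 ± 0.292, and all 4 tested guides were called lower. RDX, which encodes radixin, a linker of actin to the membrane, had 1093 and 11.9 CPM, with 2 of 4 guides called lower. The others among the 10 were hsa-mir-4725, ITGB1BP1, hsa-mir-647, MSRB1, ZNF549, PLEKHG3 and PPP1R3C. None of them passed, with exact adjusted p of 0.650 or above.

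Among the single guides with the largest fold changes was a non-targeting control, NonTargetingControlGuideForHuman_0106, which went from 39.9 to 34408 CPM. With it stood guides to WFDC13, C6 (a complement component), GLTPD2, EMR2 (now ADGRE2), LAMA2 (a laminin chain), FABP3 (a fatty acid carrier), ALDH4A1 and ZNF596, each at a log2 fold change of 12.08 or above. The WFDC13 guide HGLibB_54194 went from 43.1 ± 2.29 to 44458 ± 6013.8 CPM, 4.45% of Nutlin reads. Of 31 other guides of these 8 genes, 3 were called higher. In all, 10732 guides were called higher and 30454 lower of 86484, and 16596 of the lower ones had no read in any Nutlin library. With the replicate number as a block, 8922 guides were called higher and 11818 lower. The median guide lay at −1.32 on the TMM scale, and every fold change is to be read against it. On library totals it lay at −4.07, a shift of −2.75, and 2129 guides were called higher and 72292 lower, so that 2.86% rather than 26.1% of calls were higher.

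Guide reads were far less evenly spread after Nutlin-3a. In DMSO libraries 89.1% ± 0.429 of guides had a read, and 46.7% ± 1.98 in Nutlin libraries (SD, n = 3). The Gini index was 0.717 ± 0.00205 and 0.973 ± 0.00158. The 10 most abundant guides held 0.688% ± 0.0190 and 36.4% ± 3.53 of reads, and the top 1% held 17.6% ± 0.159 and 81.3% ± 0.761. Each of these measures separated all 3 Nutlin from all 3 DMSO libraries (exact two-sided permutation p = 0.1, the smallest possible), while library totals did not (exact p = 0.2).

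**Figure D2:**
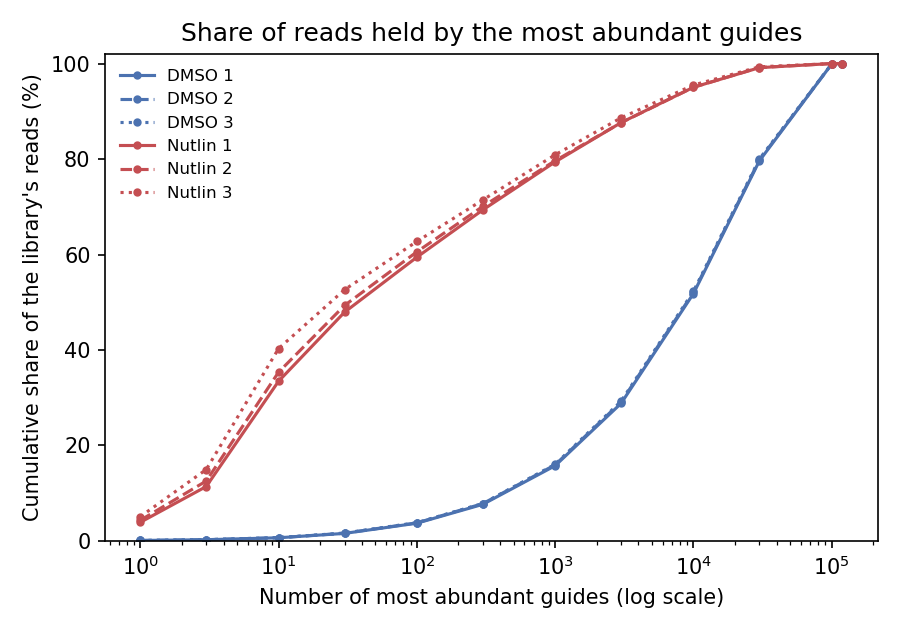
Cumulative percent of reads (y) held by the most abundant guides, ranked within each library (x, log axis), one line per library. The 1000 most abundant guides held 15.8 to 16.1% of reads in DMSO libraries and 79.4 to 80.9% in Nutlin libraries.

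Non-targeting guides, designed to match no site in the genome, were also called often. Of 959 tested, 164 were called higher (17.1%) and 292 lower (30.4%), and their median log2 fold change was −0.98 with an SD of 3.02 across guides. As a share called in either direction they were at 47.6%, as were targeting guides (odds ratio 0.997, Fisher's exact two-sided p = 0.974). Non-targeting guides were called higher more often than targeting guides (odds ratio 1.46, 95% interval 1.23 to 1.74, Fisher's exact p = 2.17e-05, adjusted over 3 comparisons p = 6.51e-05) and lower less often (odds ratio 0.804, adjusted p = 0.00264). They started at a higher median DMSO count, 318 against 136. Within strata of DMSO count, a comparison chosen after the data were seen, the odds ratio of a higher call was 0.877 (95% interval 0.735 to 1.05) and that of a lower call 0.949 (95% interval 0.824 to 1.09), so neither difference held.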

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

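The exact null, camera on ranks and the strata of DMSO count were chosen after the data were seen; the others were planned. On library totals, 2129 guides were called higher and 72292 lower, 1 list shifted, the non-targeting median was −3.75 and the odds ratio of a higher call of non-targeting guides was 1.42 (Fisher's exact p = 0.0581); the cause was not tested. With RLE factors that median was −1.18, and with a DMSO mean of at least 50 counts −0.77. With the replicate number as a block, 11818 guides were called lower and 0 lists passed. Leaving out each library in turn gave 8330 to 12089 guides higher, 23436 to 33604 lower and 2 lists in each case. No list passed with an estimated correlation (0) or on ranks (0), while fry called 25. Summed gene counts gave 5730 and 5735 genes higher and lower, and fry per gene 2005 and 9550; the cause was not tested. With the exact null, 0 genes passed with library A alone, for a cause that was not tested. Without the best guide of each gene 0 passed too, but the null did not allow for that removal, which makes its p-values too large. Only 127 genes in the higher and 111 in the lower direction then had an unadjusted p below 0.05 by random guide sets, against 882 and 871 in the main setting. That 0 is therefore no measure of concordance. With the exact null, 1 gene passed with library B alone and in each scaling, filter, block, left-out library and DESeq2 setting. The odds ratio within strata of DMSO count was 0.877, reversed from 1.46. Of results on single genes, guides and lists, 657 kept their side of the threshold and 9 became weaker. Most of the 657 were genes that missed the threshold in the main setting and missed it again. The 9 had all passed in the main setting, so these counts do not measure how firm the passing results were. The gene p-values are one-sided and do not record a change of sign: on library totals the medians of BAX, BBC3 and PMAIP1 turned to −0.98, −0.72 and −1.27, and 6592 called guides changed sign. With all libraries thinned to the same total, the Nutlin minus DMSO difference in guides detected was −42.7 percentage points, against −42.4.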

Other observations

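The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries, which were planned. Before any Nutlin-3a, guide levels in the DMSO libraries already differed between lists of genes. Guides to ribosomal proteins, needed by every cell, had a median of 0.488 CPM, those to proteasome subunits 0.511 and to the spliceosome core 1.11. Guides to olfactory receptors, which such cells are not thought to need, had 3.28, and non-targeting guides 11.1. Of ribosomal protein guides, 21.9% had no read in any DMSO library, against 3.86% of olfactory receptor guides. No library from before transduction was analysed here, so whether these differences were there from the start is not known.

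Within the p53 pathway, the same DMSO libraries held BAX guides at the 97.8th percentile of 18163 genes with 6 guides, PMAIP1 guides at 99.3, BBC3 guides at 61.4 and CDKN1A guides at 45.2, with MDM2 and PPM1D, which restrain p53, at 2.74 and 2.46. The 4 p53 inhibitors among the 13 genes named in every case had a mean percentile of 10.5 and the 9 others 75.2, with a range from 37.2 to 99.3. Sets of random genes reached so large a difference with a two-sided permutation p = 2e-05, and sets of olfactory receptor genes also with p = 2e-05, but the contrast was noticed on these 13 genes and then tested on them. The other members of the same lists did not show it, with a mean percentile of 46.7 for 13 other p53 inhibitors and 44.96 for 74 other activators, targets and pro-apoptotic genes (two-sided permutation p = 0.843). Whole-list median levels were 2.05 CPM for p53 inhibitors, 2.41 for activators and 2.29 for arrest and repair targets. The pro-apoptotic list, which holds BAX, BBC3 and PMAIP1, was higher, at 3.80 CPM. Whether knockout altered growth before Nutlin-3a, or guide numbers were uneven from the start, cannot be told apart, as starting levels were not measured.

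The 50 most abundant Nutlin guides among those called higher, leaving out guides of genes that passed the gene test, held 50.5% of Nutlin reads and 0.505% of DMSO reads. Of 184 other guides of their genes, 11.96% were called higher, against 12.3% of the remaining targeting guides (odds ratio 0.968, 95% interval 0.590 to 1.52). For these guides, this argues against knockout of the targeted gene as the general cause. Genes whose guides concurred enough to pass were left out, so it does not speak to them. Several guides carried by 1 expanding clone would be expected to share levels. Over the 50 guides, the correlation of differences in DMSO level with differences between Nutlin libraries was −0.0102 (one-sided permutation p = 0.562). A DMSO level sums over all cells with a guide, so this leaves the clone open. Some guides to unrelated genes did have like levels. Guides to WFDC13, C6 and EMR2 had 43.1, 42.6 and 49.5 CPM with DMSO. Their ratios of Nutlin 3 over Nutlin 1 were 1.30, 1.31 and 1.32. Guides to SOWAHB and CYTH2, at 53.2 and 47.4 CPM with DMSO, had ratios of 0.550 and 0.770. These guides were picked after the values were seen. Resistance that is independent of the guide may apply: 2 of the 50 were non-targeting (odds ratio 3.72, interval 0.438 to 14.2), too few to decide. The reading of these last 2 tests, and of the division of 1 population below, was made less firm after the values were seen.

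The 3 Nutlin libraries shared guide levels that DMSO libraries did not. Among 210 non-targeting guides with 300 to 600 mean DMSO counts, correlations across guides between Nutlin libraries were at least 0.808. As these guides have no target, this argues against an effect of the targeted gene as the whole cause. Correlations were −0.0152 to 0.125 between DMSO and Nutlin libraries and 0.537 to 0.636 between DMSO libraries. The narrow window of DMSO counts by itself lowers correlations with a DMSO library. Without this window, rank correlations were 0.594 to 0.610 between DMSO and Nutlin libraries. They were 0.733 to 0.743 between Nutlin libraries and 0.945 to 0.949 between DMSO libraries. Guides are not independent replicates. Division of 1 selected population into 3 samples may be a candidate explanation: 0.886% of guides with at least 50 reads in 1 Nutlin library had none in another (range 0.427 to 1.46), against 0.0179% in DMSO libraries. Counting error alone in 1 population would give 1.12e-13%, which goes against a plain division, but losses of cells or DNA and PCR were not measured and the range spans the 1% limit set for it, so it stays open.

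The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 41186 guide calls and the highest other 0, so 1 split reached it. With the exact null it gave 1 gene and the highest other, DMSO 1 with Nutlin 2 and 3, also 1, so 2 splits reached it. It gave 2 list shifts and the highest other 0, so 1 split reached it.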
